A study of Mus musculus with 2 samples.

How the data were processed

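BUD31 RIP-seq was performed on germ cells of postnatal day 14 C57BL/6J mouse testis, released by enzymatic digestion in 2 steps, per the labels' protocols. There were 2 libraries, 1 from the anti-BUD31 immunoprecipitation and 1 from input RNA, and the groups were taken from the sample titles. Reads were aligned to mm10 with TopHat2 2.0.13, per the submitters' processing notes. The peak caller, its threshold, how the input entered the call and the annotation release are not given in the sources used here.

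The deposited data are 1 annotated peak list. Per the file headers it gives for each peak a running number, the chromosome, start and end, an annotation class (intron, exon, 5′ or 3′ UTR, upstream, downstream, intergenic), a transcript, a gene symbol and number, a description and the kind of gene. It holds no fold, score, p-value, read count or strand, so depth is unknown, and a peak's strength could not be used. Every width, and every start less 1, is a whole multiple of a bin that is fixed per chromosome, from 200 bp on most to 230 bp on the X chromosome, which limits the resolution of every position. The running numbers reach 65288, and 48957 of them have no peak in the list. Between neighbouring peaks of the same gene 37.9% of 12939 pairs skip a number, so the list holds a part of a longer numbered set and what separated the 2 parts is not given. All intervals were distinct.

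Gene numbers were matched to a reference gene table of the GRCm38.p6 assembly, which is the mm10 assembly, with the start, end and kind of each gene. Of the 3258 genes in the list 3213 matched and 45 did not. Coordinates of genes come from that table and coordinates of peaks from the list, both 1-based. A gene counts as having a peak when the authors' annotation names it, whatever the class. The background was every protein-coding gene on a chromosome with at least 1 peak (14864 genes, 18.8% with a peak), and for the noncoding lists every gene there. Covered length is the overlap of the peaks assigned to a gene with the gene's extent. Peaks were also compared with 100 random placements of the same widths on the same chromosome, counting an overlap of at least 1 bp with any gene.

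Gene lists were fixed before the data were examined: 22 lists for germ cell stages, somatic testis cells, splicing, the cell cycle, chromatin and noncoding RNA. Of these 20 had at least 5 members on chromosomes with peaks. The mitochondrially encoded genes and the replication-dependent histones had none there and were not scored. Each list's share was given as a percentile among 10000 random lists matched on decile of gene span. Dnmt3b, Uhrf1 and Dnmt3l stand in 2 lists each. A member written as Speedya did not match by name. Its gene, Spdya, had 4 intron peaks on chromosome 17, 2 of which also overlap Trmt61b, and was not counted. On simulated lists of 33 genes among the 14864, 2.5% of 200 lists with an unchanged share lay above the 97.5th percentile, and 68% of 200 lists with a 2-fold share did. With matching on chromosome and span these were 2.5% and 88%.

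The rule for named genes, set in advance, was Bud31 and Cdk2, the 20 genes with the strongest peak by fold or score, the 10 genes with the most peaks, and per list up to 4 members by strength, with members without a peak where they were 4 or fewer. Without a strength value the second part was void and the list members fell to the order of their symbols. Members chosen after their values were seen are said to be so, and a gene that the rule would name is not reported here. Further planned analyses were not run. Peak strength by class has no values here. Distance to splice sites, GC content, intronless genes and matching on exon length or exon number need a genome sequence or exon annotation, not used here. Alternatives added after the data were seen use peak width, chromosome matching and the reference table in their place. Chromosomes were called well covered when at least 10% of their coding genes had a peak, a split made after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with a fixed random seed.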

Results

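The data come from an RNA immunoprecipitation sequencing (RIP-seq) assay of BUD31, a protein of the spliceosome, in germ cells isolated from the testes of C57BL/6J mice at postnatal day 14, an age at which the first wave of spermatogenesis has entered meiotic prophase. There was 1 library of RNA recovered with an anti-BUD31 antibody and 1 input library, for which 10% of the total RNA was taken. The values used here are the authors' 16331 peaks, each a stretch of the mm10 genome with a gene and an annotation class. No read count, fold or score stands beside a peak, so the depth of both libraries is unknown and a gene can only be described by whether it has peaks, how many, and how much of it they cover. With 1 library per group there is no replicate check and no p-value. Intervals are Wilson 95% intervals and cover counting error over genes or peaks only, and neither genes nor peaks are replicates.

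The comparison of the antibody library with the input asks which RNAs were recovered with BUD31. Among 20 gene lists fixed in advance, genes of meiotic prophase, genes of the piRNA pathway, genes for SR and hnRNP splicing regulators and small structured RNAs had a peak more often than genes of similar length. A peak was found in 15 of 33 meiotic prophase genes, 8 of 16 piRNA pathway genes, 17 of 35 SR and hnRNP genes and 2 of 11 small structured RNAs. Markers of macrophages and of endothelial cells had none, in 11 and 8 genes, of which 7 and 4 lie on chromosomes with few peaks. Each share was set against 10000 random lists of the same size matched on gene span. The percentile counts random lists below the observed share plus 0.5 times those that tie with it. By chance 0.5 of the 20 lists would lie above the 97.5th percentile and these 4 did. The small structured RNAs did so in only 3 of the 6 settings tried, and the peak assigned to 1 of the 2 genes, Rnu3a, covers 0 bp of it. The libraries' expression levels are unknown, so the random lists were not matched on expression.

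The meiotic prophase list had a peak in 45.5% of its members (29.8% to 62.0%), against a random median of 24.2%, at percentile 99.35. Hfm1, a DNA helicase of meiotic crossover formation, carried 12 peaks over chromosome 5, 106840193 to 106926712, of which 11 were annotated as intron and 1 as exon. Brca2, which loads recombinases onto broken DNA, carried 7 peaks that covered 13% of the gene, and Mlh3, a crossover factor, carried 7 that covered 60.1%. Mdc1, a DNA damage adaptor of the silenced sex chromosomes, had 1 exon peak of 1000 bp at chromosome 17, 35853001 to 35854000. Among members chosen after their values were seen, Tex11 on the X chromosome had 38 peaks over 63.0% of its length, Scml2 had 37 over 61.7% and Sycp2, a protein of the chromosome axis, had 20 over 17.3%. Sycp3 and Spo11, chosen likewise, had 1 intron peak each, of 1000 bp and 200 bp, and Dmc1, Prdm9 and Meioc had none. The last 3 lie on chromosomes 15, 17 and 11, where only 3.87%, 3.02% and 0.0622% of coding genes had a peak. The single peak assigned to Tex14, at chromosome 11, 87422866 to 87423275, lies over the U1 small nuclear RNA gene Rnu1a1 at 87422867 to 87423030 inside a Tex14 intron, and was singled out after it was seen. Without it the list had 14 members with a peak and stood at percentile 98.2.

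For the piRNA pathway the share was 50% (28.0% to 72.0%) against a random median of 25%, at percentile 98.4. Mael carried 14 peaks, 10 of them in introns, 3 annotated as intergenic and 1 as downstream. Fkbp6 and Mov10l1, both needed for piRNA production, carried 9 intron peaks each, over 19% and 32.4% of the gene. Of the Mov10l1 peaks, 1 of 600 bp lies over a small nuclear RNA gene, Gm23737. Mybl1, the transcription factor of pachytene piRNA precursors, carried 8 peaks that covered 81.3% of chromosome 1, 9667407 to 9700439. Named after their values were seen, Tdrd9 had 12 peaks, Tdrd5 had 10 and Piwil1, a PIWI protein, had 4.

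SR and hnRNP genes had a peak in 48.6% of members (33% to 64.4%), against a random median of 17.1%, and their share lay above that of all 10000 random lists. Hnrnpa1 had 1 peak in its 3′ UTR, at chromosome 15, 103244201 to 103245000. Hnrnpa3 had 1 exon peak at chromosome 2, 75665601 to 75666200, and Hnrnpdl had 1 exon peak and 1 peak in the 3′ UTR. The 1 peak assigned to Clk1, a kinase of SR proteins, was annotated as intergenic. Chosen after their values were seen, Rbm39 had 11 peaks, Rbm25 had 8, Pcbp2 had 6 and Srsf3 had 3. When only chromosomes in which at least 10% of coding genes had a peak were kept, a choice made after seeing the data, 7 of 12 members had a peak and the list fell to percentile 95.9, below the 97.5th. On the thinly covered chromosomes 10 of 23 members had one.

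**Figure D1:**
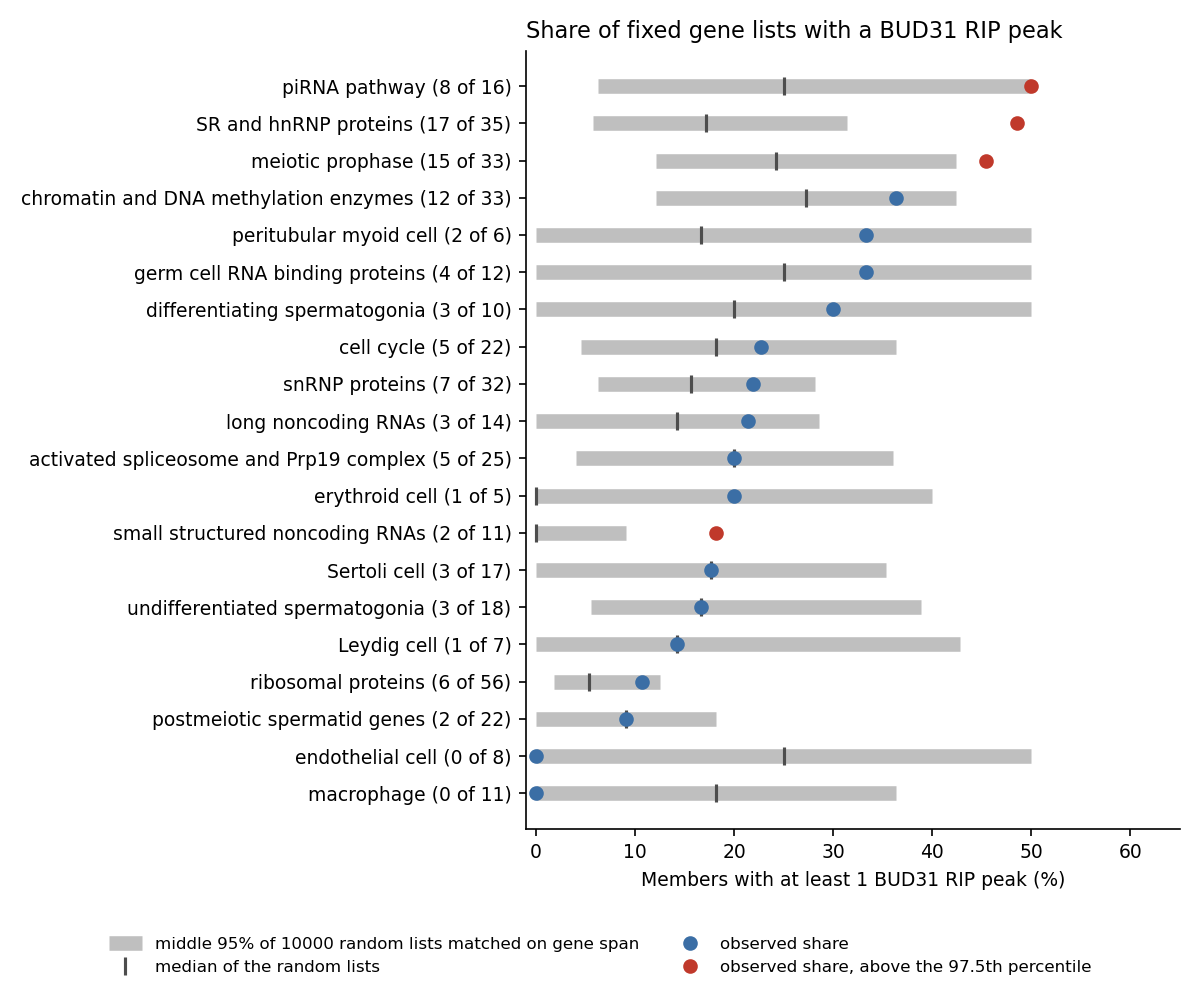
Share of the members of each fixed gene list with at least 1 BUD31 RIP peak (points, x axis in %), with the median (tick) and the middle 95% (bar) of 10000 random lists matched on gene span. Red points are the 4 lists above the 97.5th percentile; the piRNA pathway point at 50% meets the end of its bar because the percentile counts ties in part.

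Lists of other germ cell stages lay within the middle 95% of the random lists. Undifferentiated spermatogonia markers had a peak in 3 of 18 genes (16.7%, percentile 44.6). These were Taf4b with 6 peaks, Etv5, a transcription factor of stem cell self-renewal, with 2, and Sox3 with 1 exon peak that covered the whole gene. Of 10 differentiating spermatogonia markers 3 had a peak (percentile 73.3): Kit, the receptor of stem cell factor, with 3 intron peaks, and the X-linked homeobox genes Esx1 and Rhox13 with 2 each. Both Rhox13 peaks also overlap the long noncoding RNA gene Gm39506. Germ cell RNA-binding proteins had a peak in 4 of 12 genes (percentile 76.9). Boll carried 16 peaks over 53.2% of its length, Pum2 carried 10 and Ythdc1 carried 3 in introns, whereas all 3 peaks of Celf1 lay in its 3′ UTR. Postmeiotic spermatid genes had a peak in 2 of 22 (percentile 59.0), and neither lay in the gene by the authors' classes. The peak of Tnp2 was annotated as downstream, although it spans the whole gene and also overlaps Socs1, and the 3 peaks of Akap4 were intergenic. Prm1, Prm2 and Tnp1, chosen after their values were seen, had none.

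Genes for the machinery that BUD31 belongs to lay within the middle 95% of lists matched on span. The activated spliceosome and Prp19 complex list had a peak in 5 of 25 genes (20%, percentile 54.3), against a random median of 20%. On the well covered chromosomes alone it had 5 of 10, against a random median of 30%, at percentile 92.4. Dhx15, a helicase of spliceosome disassembly, had 3 peaks, and Rbm22 and Fam50a had 1 intron peak each. Small nuclear ribonucleoprotein (snRNP) proteins had a peak in 7 of 32 genes (21.9%, percentile 79.99). Sf3b1, a branch site factor, had 6 peaks over 59.9% of its length, Sf3b3 had 2, and Sf3a2 and Sf3b6 had 1 each. Matched on chromosome as well as span, a choice made after seeing the data, the snRNP list rose to percentile 98.7, and on the well covered chromosomes it stood at 98.03 with 6 of 13. Ribosomal protein genes had a peak in 6 of 56 (10.7%, percentile 89.5), above a random median of 5.36%. Without matching on span the random median was 17.9% and the list lay below it, at percentile 5.66. Those of Rpl10l and Rpl37a were annotated as intergenic, although the latter covers 60.4% of its gene, and Rpl32l and Rpl36a had exon peaks. Reads of ribosomal protein genes can be shared with near-identical copies, so these calls are uncertain.

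Cdk2, a kinase required in meiotic prophase, had 1 peak, annotated as exon, at chromosome 10, 128702801 to 128704800. It covers 28.1% of the gene, which runs from 128697938 to 128705051, and the reference table also places Pmel over the same stretch. Bud31 itself had 1 peak of 400 bp, annotated as 3′ UTR, at chromosome 5, 145147801 to 145148200, which also overlaps Ptcd1. The list gives no strand, so overlapping genes cannot be separated, and the class is given once per peak, so a peak of 2000 bp can reach beyond the exon it is named for. The cell cycle list as a whole had a peak in 5 of 22 genes (22.7%, percentile 65.2). Ccnb3, a meiotic cyclin, carried 11 peaks over 60.4% of its length, Cdk6 carried 3 and Cdc25c carried 2.

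**Figure D2:**
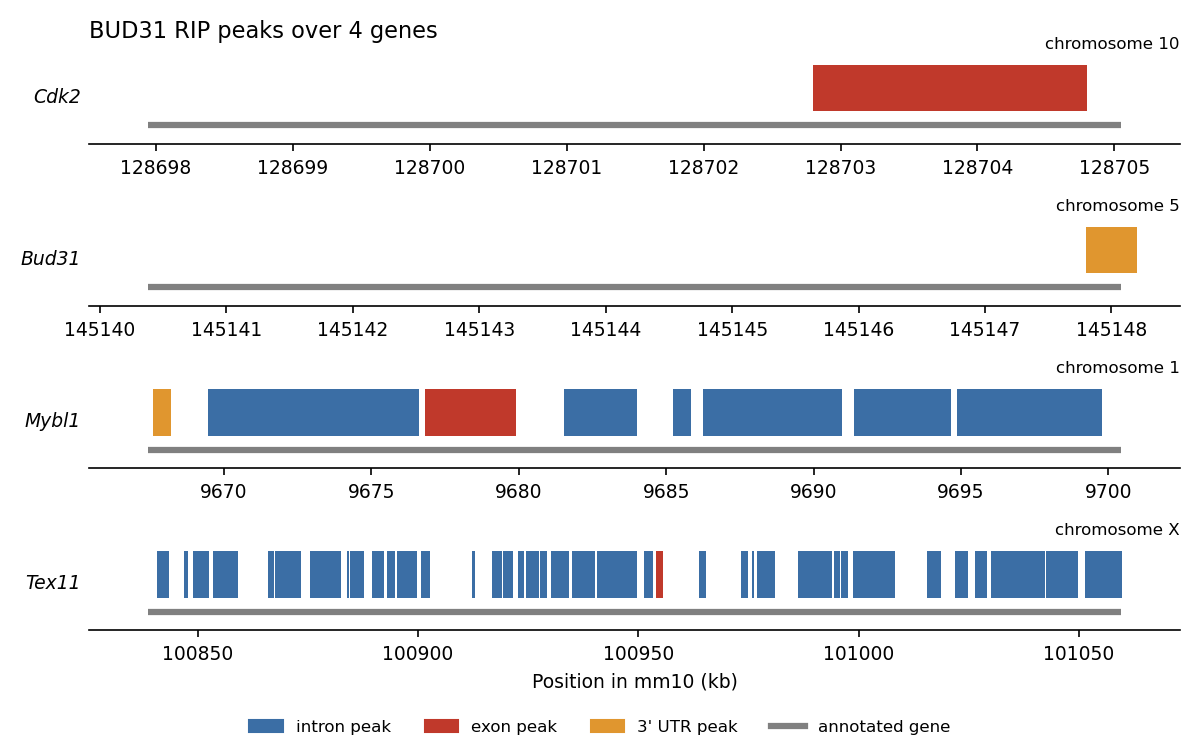
BUD31 RIP peaks (boxes, coloured by the authors' annotation class) over the annotated extent (grey line) of Cdk2, Bud31, Mybl1 and Tex11, with mm10 position in kb on each x axis. Cdk2 and Bud31 have 1 peak each, whereas 8 peaks cover 81.3% of Mybl1 and 38 cover 63.0% of Tex11.

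Chromatin and DNA methylation enzymes had a peak in 12 of 33 genes (36.4%, percentile 88.7). Dnmt3a, a de novo DNA methyltransferase, had 6 peaks, Brdt, a testis bromodomain protein, had 3, Hdac2 had 2 and Dot1l had 1. Chosen after their values were seen, Kdm5b had 25 peaks and the X-linked demethylase Kdm6a had 11 over 83.8% of its length. On the well covered chromosomes alone, a choice made after seeing the data, 12 of 15 members had a peak and the list rose to percentile 99.35.

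Markers of the somatic cells of the testis had a peak in 7 of 54 genes over 6 lists (13%, 6.42% to 24.4%), at percentile 17.2. Sertoli cell markers had a peak in 3 of 17 genes (percentile 57.0): Kitl with 6 intron peaks, Wt1 with 1 intron peak of 200 bp and Aard with 1 in the 3′ UTR. Leydig cell markers had 1 of 7 (percentile 43.3), in the 3′ UTR of Pdgfra. Peritubular myoid cell markers had 2 of 6 (percentile 72.8), with 15 peaks in Mylk, 1 in Myh11 and none in Acta2, Dcn, Des or Myl9. Of 5 erythroid markers only Alas2 had peaks (percentile 69.9), and both also overlap Apex2. Slc4a1 and the globin genes Hba-a1 and Hba-a2 had none, but all lie on chromosome 11, where 1 of 1609 coding genes had a peak. The macrophage and endothelial lists, with no member with a peak, stood at percentiles 7.01 and 5.32, and their intervals allow shares of up to 25.9% and 32.4%. Of their members 7 of 11 and 4 of 8 lie on the thinly covered chromosomes. Matched on chromosome and span the percentiles were 6.9 and 7.5.

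Among noncoding RNAs, long noncoding RNAs had a peak in 3 of 14 genes (percentile 84.8). All 6 peaks of Malat1, an abundant nuclear RNA, lay in its exon and covered 64.0% of chromosome 19, 5795690 to 5802672. Xist, the RNA of X inactivation, had 4 exon peaks that covered 9890 bp, and Meg3 had 1 exon and 1 intron peak. Of 11 small structured RNAs 2 had a peak (percentile 99.75). Rmrp, the RNA of RNase MRP, had 1 exon peak at chromosome 4, 43492681 to 43492890, and 1 upstream peak, whereas the peak assigned to Rnu3a was intergenic and covered 0 bp of it. Without matching on span this list stood at percentile 81.8, and with genes that overlap a peak in the reference table, which counts Rnu1a1 and not Rnu3a, at 97.15.

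In total the peaks named 3258 genes and covered 42.5 Mb. Their width ran from 200 to 60260 bp with a median of 1400 bp (interquartile range 615 to 3075). By the authors' classes introns held 13358 peaks (81.8%, 81.2% to 82.4%). Exons held 817 (5.0%), 3′ UTRs 783 (4.79%) and 5′ UTRs 105 (0.643%). Another 1098 peaks (6.72%) were intergenic. With 1 class per peak, a wide peak named intron can also cover exons. A peak of 5980 bp over 98.1% of Hnrnph2 and a peak of 12800 bp over 99.95% of Snrpd1 were both annotated as intron. When 1 peak was kept per gene, the widest, the share in exons and UTRs was 17% against 10.4% over all peaks. Genes overlapped 93.8% of the peaks, and random placement of the same intervals on the same chromosomes gave a median of 47.7%, with 48.8% as the highest of 100 placements.

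Peaks were concentrated in long genes. The 10 genes with the most peaks held 1068, at spans of 206 to 1106 kb. Rabgap1l led with 154 peaks over 50.9% of its length, followed by Auts2 with 135 over 9.46%, Smyd3 with 126, Spag16, a sperm flagellar gene, with 108, and Sdk1 with 105. The X-linked formin gene Diaph2 had 100, Immp2l had 92, Rasal2 had 90, the dynein gene Dnah14 had 81 and Cdc42bpa had 77. The 407 genes with at least 10 peaks held 51.6% of all peaks, while 1126 genes had 1. On the well covered chromosomes the share of coding genes with a peak was 5.85% in the shortest decile of gene span, 56.9% in the next to longest and 46.8% in the longest.

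X-linked genes had a peak more often than autosomal genes of the same length. A peak was found in 469 of 966 coding genes on the X chromosome (48.6%, 45.4% to 51.7%) and in 2156 of 6383 on the 7 well covered autosomes (33.8%, 32.6% to 34.9%). Peaks outside genes count towards the gene they name, and they made up 15.5% of peaks on the X chromosome and 4.64% to 9.54% on those autosomes. Counting genes that overlap a peak in the reference table, 46.4% of X-linked coding genes had one. The autosomal share by that count is not given here, so the 46.4% cannot be set against the 33.8%. The X share was above the autosomal one in all 5 span groups, with 19.2% against 7.55% in the shortest and 78.1% against 48.8% in the longest. In the middle group the intervals touched, at 40.7% to 55.4% against 35.4% to 40.7%. There were 3.52 peaks per coding gene on the X chromosome and 1.94 on those autosomes together. This did not hold against each of them: chromosome 1 had 3.99 and chromosome 12 had 3.27, while chromosomes 8 and 10 had 0.251 and 0.833. In the share of genes with a peak the autosomes ran from 14.7% on chromosome 8 to 44.2% (40.5% to 47.9%) on chromosome 12, whose interval overlaps that of the X chromosome. The bin behind the positions was 230 bp on the X chromosome and 200 or 205 bp on those autosomes. Of the running numbers from its first to its last peak, the X chromosome kept 3404 of 5097, a larger part than any of those autosomes. Chromosome 1 kept 4806 of 16089 and chromosome 8 kept 262 of 4799. What removed the other numbers is not given, so the X excess cannot be told apart from unequal removal of peaks.

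Peaks were unevenly spread over the chromosomes. Chromosomes 1, 5, 8, 10, 12, 16, 18 and X held 15791 of the 16331 peaks (96.7%). Chromosomes 2, 4, 11, 15, 17 and 19 held 520, and 166 of their 7259 coding genes (2.29%, 1.97% to 2.66%) had one. On chromosome 19 the peaks were those of Malat1, on chromosome 4 those of Rmrp, and on chromosome 11 the single peak over Rnu1a1. Exons and UTRs held 25% of peaks on the thinly covered chromosomes (21.5% to 28.9%) and 9.96% on the well covered ones (9.50% to 10.4%). Chromosome Y held 20 peaks. Chromosomes 3, 6, 7, 9, 13 and 14 have no peak in the list and were not analysed here. Their absence does not show that no peak was called there. The running numbers skip from 25481 on chromosome 12 to 29212 on chromosome 15. They also skip from 34471 on chromosome 2 to 39806 on chromosome 4, and from 49115 on chromosome 5 to 55295 on chromosome 8. Which chromosomes the skipped numbers belonged to is not given.

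**Figure D3:**
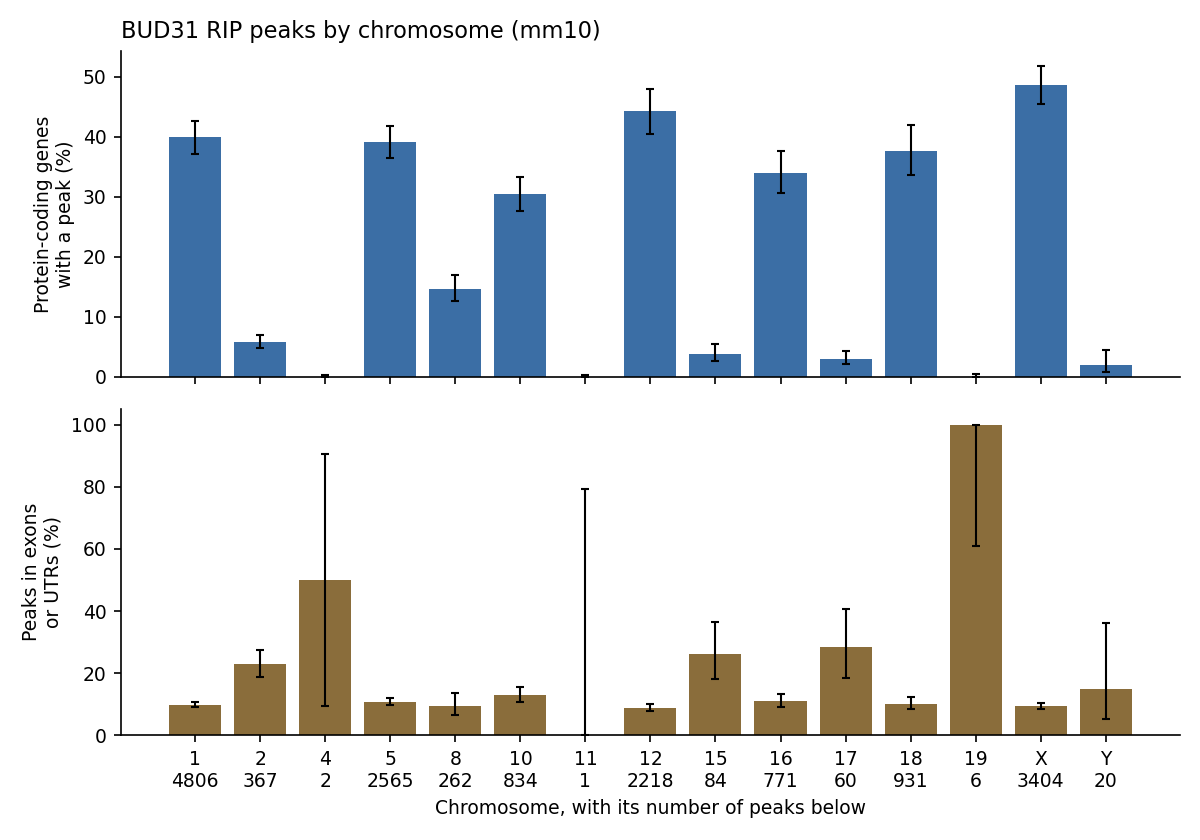
Percent of protein-coding genes with a BUD31 RIP peak (upper bars) and percent of peaks in exons or UTRs (lower bars) on each chromosome with peaks, with Wilson 95% intervals as error bars and the number of peaks under each chromosome. The X chromosome has the highest share of genes with a peak at 48.6%, and all 6 peaks of chromosome 19 are exon peaks of Malat1.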

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

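The meiotic prophase list stayed above the 97.5th percentile in all 7 settings, the reported one included, (percentile 99.07 to 100) and the piRNA pathway in all 7 (98.1 to 99.8). SR and hnRNP genes did so in 6 of 7 and fell to 95.9 on the well covered chromosomes, where only 12 members remain. Small structured RNAs did so in 3 of 6 (81.8 to 99.99), snRNP proteins in 2 of 7 (67.9 to 98.7) and chromatin enzymes in 2 of 7 (87.2 to 99.35); the cause was not tested. The other settings were no matching and peaks inside the gene body, both planned, and, added after seeing the data, matching on chromosome and span, well covered chromosomes, wider peaks and genes overlapping a peak in the reference table. Of 114 recomputed differences between a list and its random median, 106 stayed within the counting interval and 8 moved beyond it. Of these 1 changed sign: without matching on span the ribosomal protein genes lay below the random median (17.9%) instead of above it, at percentile 5.66. The activated spliceosome list rose from 0 to 20 points above its random median on the well covered chromosomes, at percentile 92.4.

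Keeping the peaks at or above their chromosome's median width left 8958 peaks by construction, with 82.8% in introns and 6.98% outside genes, and 37.8% of X-linked coding genes with a peak. The autosomal share of genes in this setting is not given here. Peaks per coding gene on the X chromosome were then 1.80 times those of the well covered autosomes. Keeping the widest peak per gene gave 70.6% in introns, 17% in exons and UTRs and 12.4% outside genes, since genes with many intron peaks then count once. Weighted by covered bases these shares were 84.5%, 8.24% and 7.27%. Per Mb between the first and last gene, the X chromosome had 1.46 times the peaks of the well covered autosomes, against 1.82 times per coding gene. Merging touching peaks left the count at 16331, and merging peaks at most 1 bin apart, added after seeing the data, gave 14389. Alternatives on peak strength or threshold, exon overlap, exon length or number, splice site distance, GC content and intronless genes, named before the data were examined, were not run, for want of such values or of a genome. No paired analysis was possible because each group has 1 library. Unknown depth leaves the absence of a peak uninformative about binding or expression.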

Other observations

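All gene families and genes in these first paragraphs, and the tests of the 3 patterns after them, were chosen after the data were seen. Of 127 families of at least 12 coding genes that share a symbol prefix, 9 lay above the 97.5th percentile of random lists under both matchings, on span and on chromosome and span, and 14 lay below the 2.5th under both. By chance 3.175 would fall in each tail of 1 matching. DEAD-box helicases (Ddx) had a peak in 13 of 28 genes against a random median of 21.4%, with Ddx1 covered over 80.4% of its length and the X-linked Ddx3x over 83.5%. Ubiquitin-specific proteases (Usp) had a peak in 18 of 35, led by Usp12 with 16 peaks and the X-linked Usp26 with 14. Genes with the prefix Eif, translation initiation factors and some of their regulators, had a peak in 16 of 43 and RNA polymerase subunits (Polr) in 7 of 18. Olfactory receptors (Olfr) had a peak in 3 of 659, vomeronasal receptors (Vmn) in 1 of 72 and cytochrome P450 genes (Cyp) in 2 of 76. These are 0.455%, 1.39% and 2.63%, against random medians of 1.97%, 12.5% and 10.5%. Members of the X-linked Rhox cluster had a peak in 2 of 33, at percentile 0 among lists matched on chromosome and span and 21.1 on span alone. Family members in 1 cluster are not independent, and near-identical copies can share reads.

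Some genes were covered nearly end to end. Of 1980 coding genes of at least 20000 bp with a peak, the median was covered over 12% (interquartile range 3.47% to 36.9%), and 59 were covered over more than 80%. Of these 59, 30 are X-linked, among them Hprt at 92.5% and Kdm5c at 81.4%. The X-linked genes of that length with a peak number 276, and their median covered share was 40.3%. Chromosomes 18, 12 and 1 were nearest, at 34.4%, 34.2% and 31.5%, with 7, 10 and 12 genes covered over more than 80%. Chromosomes 5, 16, 10 and 8 ran from 9.21% down to 2.61% and had 0 such genes. The X chromosome also kept a larger part of its running numbers than these autosomes, so unequal removal of peaks could raise its covered share. Over the Xist locus, peaks covered 9890 bp of Xist and 0 bp of its antisense gene Tsix outside Xist, which is chromosome X, 103431517 to 103460372 and 103483234 to 103484957. A peak of at most 1000 bp lay over 9 small structured RNA genes, including Rnu1a1, Rmrp and the small nucleolar RNA Snord59a in an intron of Atp5b.

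The first pattern is the scarcity of peaks on chromosomes 2, 4, 11, 15, 17 and 19. Removal of peaks after numbering cannot account for it on chromosomes 11, 17 and 19, since the running numbers leave room for at most 83 on any of them. Peaks dropped before numbering would leave no gap and stay possible. Gene length cannot account for the scarcity, since 2.29% of coding genes had a peak where 32.6% would from their spans. Gene content does not account for it as a whole: of the members of 18 fixed lists of coding genes, 19 of 207 had a peak there (9.18%, 5.95% to 13.9%), where 48.9% would at each list's share on the well covered chromosomes. The thin chromosomes were lower beyond the counting intervals in 5 of the 18 lists, such as chromatin enzymes with 0 of 18 against 12 of 15 and meiotic prophase with 4 of 20 against 11 of 13, but not for SR and hnRNP genes with 10 of 23 against 7 of 12. A calling threshold that differs between chromosomes may contribute, since peaks on the thin chromosomes lay in exons and UTRs more often (25% against 9.96%). Ribosomal protein genes, with abundant mRNAs, cannot decide this. There 0 of 28 had a peak, but random lists on these chromosomes also had a median of 0%, and the list stood at percentile 42.5. Chromosome 8 had 0.251 peaks per coding gene, near the 0.206 of chromosome 2, and exons and UTRs held 9.54% of its peaks against 22.9%. This pair cannot decide it either, since chromosome 8 kept 262 of 4799 running numbers and chromosome 2 kept 367 of 410. Their median peak widths also differed, at 1200 and 400 bp. No biological explanation was tested.

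The second pattern is the high share of meiotic, piRNA and SR or hnRNP genes with a peak. These lists were singled out by their percentiles among span-matched lists, so those percentiles are no further test of gene length. Placement of the lists on chromosomes does not account for it, with 99.55 as the lowest of the 3 percentiles after matching on chromosome and span, although the SR and hnRNP list stood at 95.9 on the well covered chromosomes alone. RNA abundance stays open: the ribosomal protein genes, with abundant mRNAs, stood at percentile 89.4 of lists matched on chromosome and span, neither above the 97.5th nor below the 50th. Preferred binding of these RNAs by BUD31 and higher expression of these genes in the cells cannot be told apart without the libraries' read counts.

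The third pattern is that 81.8% of peaks were annotated as intron. Random placements within genes by class were not run, so whether this exceeds what the length of introns would give is unknown. Genomic DNA in the libraries would place peaks without regard to genes, and on chromosomes 2 and 15, where the numbers follow position and 43 and 0 are absent between the first and last peak, 97.8% of peaks overlapped a gene (96.0% to 98.8%) against at most 60.5% in 100 random placements. For the other chromosomes the numbers absent from the list leave this less certain, since peaks outside genes could be among them. Chromosomes 2 and 15 are also thinly covered and hold 451 peaks. Exons and UTRs held 22.9% and 26.2% of these, against 9.96% on the well covered chromosomes, so the 2 may not stand for the rest. One hypothesis is that unspliced RNA was recovered with BUD31, and it was not tested, because the list has neither strand nor reads. No comparison with another antibody was analysed here, so unspliced RNA that is recovered with any antibody also stays open.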
